A study of Mus musculus with 8 samples.

How the data were processed

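Total RNA from uninduced and ephrin-B1-induced mouse embryonic palate cells was measured on single-channel Illumina bead arrays, 4 per group. The labels give column-based RNA extraction, a Bioanalyser check and biotinylated cRNA. The deposited values were exported from GenomeStudio 1.6.0, as the submitters' processing notes state. Per the file headers, the values used are an average bead intensity per probe and array on a linear scale, and they carry no normalization between arrays. The lowest signal per array was 25.2 to 42.6 and the median 69.6 to 75.9. The deposited table also gives a detection p-value per probe and array, against the negative control beads of that array. A processed matrix by the authors holds intensity values with the background subtracted and a median of 4.4 on each of the 8 arrays. Its lowest value per array was -43.3 to -29.4. The matrix served as an alternative. Its values had a Spearman correlation of 1 with the raw column of the same array and at most 0.919 with any other, so no array was mixed up between the files.

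The table had 46643 lines for 46632 probes, and 11 repeated probe identifiers were averaged. Of these probes, 29976 carried the name of 1 gene, 10 of several and 16646 of none, and 17711 genes had a probe. Of the Entrez identifiers, 99.8% matched the reference table of gene names. No genome build is named in the sources used here, so no positions are given. Signals were background corrected and quantile normalized with neqc in limma 3.58.1 under R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were kept, which left 16514 probes, 3653 of them without a single gene name. Each of the 9396 genes was represented by its brightest kept probe, and 2647 genes had more than 1.

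Induced and uninduced arrays were compared with limma (lmFit, eBayes with a variance trend, two-sided, Benjamini-Hochberg over 9396 genes, adjusted p under 0.05). The difference is induced minus uninduced. Fits with the slide or with the replicate number as a block were alternatives. The numbers pair the arrays: after subtracting each group's mean, arrays of the same number had correlations across genes of 0.607, 0.616, 0.729 and 0.651, all above the limit of 0.1, and other combinations had -0.576 to 0.38. These correlations run across genes, which are not independent replicates. The fit without a block was fixed before the data were examined, since the series design names no block. Its SEs also hold differences between replicates that both groups share. Results are given without a block and, where calls change, with each block.

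A total of 27 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members (25) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the 25, and with an estimated correlation and fry beside it. Camera compares a list with all other genes, whereas fry asks whether its genes move on balance one way. The SE of a list is over the 4 pairs. The rule named, among called genes with 1 sign in all 4 pairs, up to 15 largest rises and 10 largest falls, filled up with genes called in the slide-block fit, which gave 2 rises and 10 falls; called members of the immediate early and ERK feedback lists, up to 4 members with the smallest p of every other list, and Efnb1, Ephb1, Ephb2, Ephb3, Ephb4 and Ephb6. Named after their values were seen were the members of those 2 early lists that passed with the replicate block alone or were not called, Wnt9a, Dact1, Il11, Nppb, Rgs16, Adm, Stc1, the genes of activated macrophages other than Ptgs2, and the immune markers other than Cd52, Tyrobp, C1qa and C1qb. Of 116 named genes, 32 had more than 1 kept probe, and in 13 of these the probes differed in sign: Srebf2, Fdps, Egr3, Tbx3, Ephb4, Insig1, Rps3, Tyms, Myh9, Pdgfa, Actc1, Hspd1 and Efna5. Ephb3 and Ephb2 gave no test. For a probe above background on no array of 1 group, the difference is given as at least a fold between the other group's mean and a floor. That floor is the mean, over the arrays of the undetected group, of the lowest log2 intensity that counted as detected on each.

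Tested on simulated data with these arrays' spread, the fit without a block recovered 22.4%, 92.5% and 100% of genes shifted by 0.5, 1 and 2 on the log2 scale. With the slide block it recovered 61.2%, 100% and 100%, and with the replicate block 67.2%, 98.5% and 100%. It called 0, 1 and 4 unchanged genes in the same order, and 0 of 24 lists without a shift. The simulated noise was drawn for each probe independently, so the genes of a list did not vary together. The simulation therefore cannot show how often lists of correlated genes are called falsely. In the real arrays the estimated correlation was 0.21 for the ERK feedback list without a block.

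The alternatives were no background correction, normexp with an offset of 50, median scaling, the authors' matrix, no filter, detection p under 0.01 on all 8 arrays, eBayes without a trend, array weights, the mean of all probes of a gene, adjusted p under 0.01, slides 1 and 2 alone, slide 3 alone, and leaving out each array or each pair. The median log2 difference of all genes was -0.0015 with quantile normalization, 0.011 with median scaling and 0.025 for the raw signals. Every sample column was used. Probes without a single gene name were counted and were not part of the gene tests.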

Results

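Gene expression was measured with Illumina mouse bead arrays in MEP cells, primary cells grown from the palatal shelves of mouse embryos at stage E13.5. Palatal shelves are the outgrowths that meet and fuse to form the roof of the mouth. Cells at passage 1 were induced with pre-clustered ephrin-B1 at 2 ug/ml for 60 min on 4 arrays, and 4 arrays held uninduced cells. Ephrin-B1 is a membrane-anchored ligand of Eph receptor tyrosine kinases, and clustering lets a soluble form activate these receptors. The labels call the uninduced arrays a control induction, and do not state whether the clustering reagent alone was given. Replicate 1 of both groups was on slide 1, replicate 2 of both on slide 2, and replicates 3 and 4 of both on slide 3. Between 15303 and 17362 of 46632 probes were above background on each array, which is 32.8% to 37.2%. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the limma p-values of genes measure the spread between arrays. Camera p-values with the preset correlation set the genes of a list against all other genes, and do not measure that spread.

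The comparison of induced with uninduced cells asks which transcripts respond within 60 min to forward signaling, the signal an Eph receptor sends into its own cell. The chemokine gene Ccl4, whose product draws immune cells, rose from near background in all 4 pairs of arrays with the same replicate number. Spry4 and Dusp6 fell in all 4 pairs. Both encode feedback inhibitors of the ERK pathway, Spry4 as a Sprouty protein and Dusp6 as a phosphatase of ERK. Of 9396 genes tested with limma, 1 was higher and 2 were lower at an adjusted p under 0.05, and 119 had an unadjusted p under 0.05, of which 32 were higher and 87 lower. With median scaling in place of quantile normalization the same threshold gave 1 higher and 0 lower, with 15 higher and 41 lower at an unadjusted p under 0.05.

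Ccl4 (Entrez 20303) had a normalized log2 intensity of 4.68 ± 0.29 (SD, n = 4) in uninduced and 8.35 ± 0.57 (SD, n = 4) in induced cells. The log2 difference was 3.66 (SE 0.26, adjusted p = 0.000265, higher in 4 of 4 pairs). Its probe was not above background on any uninduced array and was above it on all 4 induced arrays, so Ccl4 was at least 8.76-fold higher. Another Ccl4 probe showed the same pattern and was at least 1.92-fold higher (adjusted p over all probes = 0.0397). Within slides the log2 difference was 4.08 on slide 1, 4.23 on slide 2 and 3.17 on slide 3, where the 4 arrays taken alone gave an adjusted p of 0.468 (range over all alternatives 9.94e-10 to 0.468).

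Spry4 (Entrez 24066) fell by 0.96 on the log2 scale (SE 0.13, adjusted p = 0.048), from 7.88 ± 0.19 to 6.92 ± 0.12 (SD, n = 4), or 1.95-fold. Dusp6 (Entrez 67603) fell by 0.76 (SE 0.094, adjusted p = 0.0345), from 10.85 ± 0.11 to 10.10 ± 0.14 (SD, n = 4), or 1.69-fold. Within slides 1, 2 and 3 the differences were -0.83, -0.92 and -1.04 for Spry4 and -0.73, -0.89 and -0.70 for Dusp6. A dimmer Dusp6 probe, above background on 2 arrays of each group, gave -0.29 (SE 0.29). Both calls were lost with median scaling (adjusted p = 0.9999 for each), without the variance trend (adjusted p = 0.0588 for Spry4 and 0.119 for Dusp6), with slides 1 and 2 or slide 3 alone, without replicate 2 in the fit with the slide block, and when any single array was left out, except that Dusp6 still passed without induced replicate 4; Dusp6 was also lost with the mean of its probes. Over all alternatives the log2 difference of Spry4 stayed between -1.04 and -0.72 (adjusted p from 3.36e-05) and that of Dusp6 between -0.81 and -0.53 (adjusted p from 2.26e-06 to 1).

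**Figure D1:**
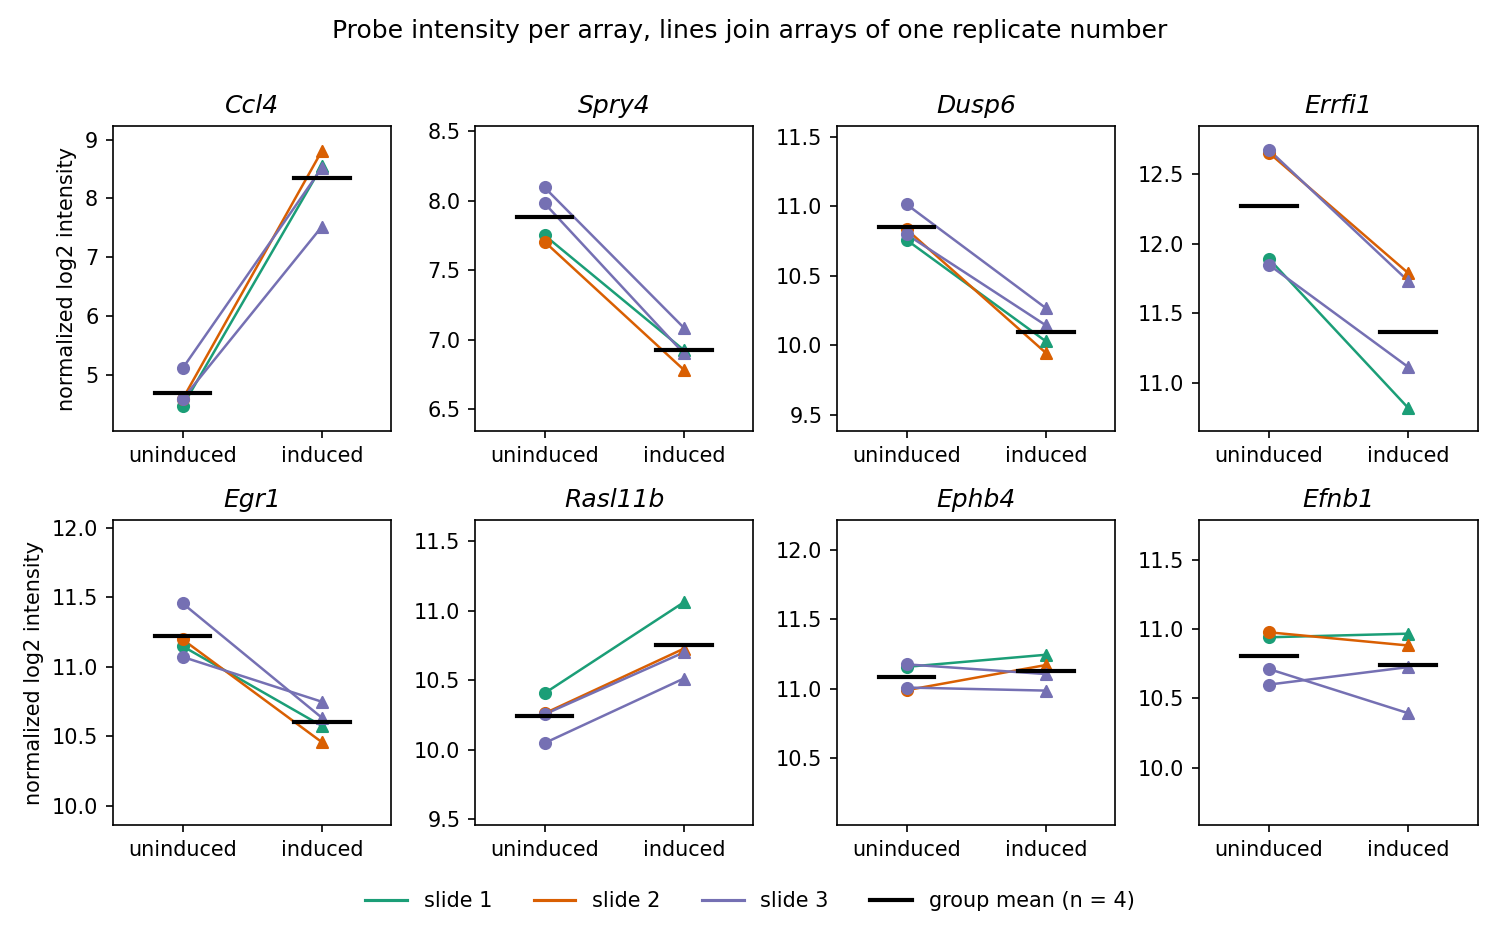
Normalized log2 probe intensity (vertical axis) of 8 genes on each uninduced (circle) and induced (triangle) array, with lines joining arrays of one replicate number, colours for slides 1 to 3 and black bars for group means (n = 4). Ccl4 went up and Spry4, Dusp6, Errfi1 and Egr1 went down along all 4 lines, while Ephb4 and Efnb1 differed by 0.04 and -0.07 between the group means.

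Arrays with the same replicate number resembled each other, and taking this pairing into account added many decreases. Most were smaller than that of Dusp6, while Errfi1, Egr3, Egr2 and Ptgs2 fell by more. With the replicate number as a block, 4 genes were higher and 46 lower, and with the slide as a block 2 were higher and 10 lower. Without the variance trend the replicate block gave 1 higher and 10 lower, with 11 of the 50 genes shared, and without 1 pair it gave 29, 21, 30 and 21 lower (without replicate 1, 2, 3 and 4), with 19 to 33 of the 50 shared. All 50 and all 12 of these genes changed in one direction in 4 of 4 pairs, and both sets held the 3 genes called without a block. The replicate block favours genes whose 4 pair differences agree, so the count of pairs is no separate support for its calls. The 46 decreases with the replicate block ranged from 0.23 to 0.96 on the log2 scale, with a median of 0.47. Errfi1, an inhibitor of the EGF receptor, was lower by 1.87-fold (log2 -0.91, SE 0.056 with the block, adjusted p = 6.8e-07, lower in 4 of 4 pairs), and without a block its SE was 0.25 and its adjusted p 0.9999. Hbegf, a ligand of the EGF receptor, was 1.51-fold lower and passed with either block (slide, adjusted p = 0.00645, lower in 4 of 4 pairs). Nuak2, a kinase related to AMPK, passed with either block too (log2 -0.49, slide, adjusted p = 0.0229, lower in 4 of 4 pairs). Rasl11b, a small GTPase of the Ras superfamily, was the other gene higher with either block, by 1.42-fold (log2 0.51, slide, adjusted p = 0.0247, higher in 4 of 4 pairs). With the replicate block, Wnt9a, a Wnt ligand, and Dact1, a Dishevelled-binding regulator of Wnt signaling, were also higher, by 1.35-fold (adjusted p = 0.00339) and 1.26-fold (adjusted p = 0.0147), each in 4 of 4 pairs. Wnt9a and Dact1 were chosen after their values were seen.

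The immediate early transcription factors, genes switched on within minutes by growth factors, were lower as a list. Of 29 members, 22 were measured, 19 had a lower mean in induced cells and 3 a higher one. Their mean log2 difference was -0.29 (SE 0.023 over 4 pairs, lower in 4 of 4 pairs, camera adjusted p = 2.66e-16), and the call held with an estimated correlation (adjusted p = 0.00201). With that correlation camera gave an adjusted p of 0.0192 with the slide block and 0.0443 with the replicate block. Fry gave 0.00214 without a block, 0.00501 with the slide block and 0.0086 with the replicate block. The mean was -0.34 on slide 1, -0.31 on slide 2 and -0.25 on slide 3. Over all genes 0 members were called by limma without a block, 2 were lower with the slide block and 8 were lower with the replicate block. Adjusted over the list alone, 4, 10 and 12 members were lower. Egr3 (-0.88, slide block adjusted p = 0.0164) and Egr1 (-0.62, slide block adjusted p = 0.0182), zinc finger factors induced by ERK, passed with either block and were lower in 4 of 4 pairs. A dimmer Egr3 probe, above background on 2 uninduced and 4 induced arrays, gave 0.26 (SE 0.15). Egr2, Myc, Atf3, Fosl1, Jun and Fosl2 passed with the replicate block alone, with log2 differences of -0.81, -0.70, -0.65, -0.39, -0.31 and -0.25 and adjusted p from 0.000203 to 0.0459, each lower in 4 of 4 pairs. Atf3 was near background, above it on 4 uninduced and 2 induced arrays. Over all alternatives Atf3 lay between -0.80 and -0.34 and Jun between -0.41 and -0.16. Fos, a partner of Jun in the AP-1 factor, was not called, with a difference of 0.02, nor was Junb, with -0.22.

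The ERK pathway feedback regulators, which restrain signaling from receptor tyrosine kinases, were lower too. Of 18 measured members, 15 had a lower and 3 a higher mean, and the list mean was -0.27 (SE 0.0093 over 4 pairs, lower in 4 of 4 pairs, camera adjusted p = 3.99e-12). This call was lost with an estimated correlation (adjusted p = 0.0845) and with fry (adjusted p = 0.196), and with an estimated correlation it passed with the slide block (adjusted p = 0.021) and the replicate block (adjusted p = 0.0443). The list median was -0.13, and the mean was -0.26 on slide 1, -0.26 on slide 2 and -0.29 on slide 3. Over all genes 2 members fell without a block (Spry4 and Dusp6), 4 were lower with the slide block and 6 with the replicate block, and adjusted over the list alone the counts were 5, 6 and 7. Dusp5, a nuclear ERK phosphatase (-0.70, slide block adjusted p = 0.0164), and Phlda1 (-0.53, slide block adjusted p = 0.0116) passed with either block, each lower in 4 of 4 pairs. Errfi1 and Dusp4 (-0.40, adjusted p = 0.0243, lower in 4 of 4 pairs) passed with the replicate block alone. Dusp1 (-0.17), Etv4 (-0.15) and Etv5 (-0.12) were not called.

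Of the 23 other tested lists, 2 were lower by camera with the preset correlation. Neither passed with an estimated correlation or with fry, with or without a block. The YAP and TEAD target genes, read-outs of a transcription factor pair that follows cell shape and tension, had a mean of -0.16 over 11 measured members, 8 of them lower (SE 0.03 over 4 pairs, lower in 4 of 4 pairs, adjusted p = 0.000311; adjusted p = 0.536 with an estimated correlation). Without induced replicate 2, which left its partner unpaired, the mean was -0.08 and the call was lost (adjusted p = 0.13). Members called over all genes numbered 0 without a block, 1 with the slide block and 3 with the replicate block, and adjusted over the list alone 2, 3 and 4. These 3 were Ankrd1, a muscle-type ankyrin repeat protein (-0.51, slide block adjusted p = 0.0302), Ccn1, a matrix-associated signaling protein (-0.34, replicate block adjusted p = 0.0209), and F3, the tissue factor of blood clotting (-0.33, replicate block adjusted p = 0.00749), each lower in 4 of 4 pairs. A dimmer Ccn1 probe, above background on all arrays of both groups, gave -0.16 (lower in 3 of 4 pairs, replicate block adjusted p over all probes = 0.704). The NF-kB and cytokine list, which does not hold Ccl4, had a mean of -0.13 over 17 members, 10 of them lower (SE 0.027 over 4 pairs, lower in 4 of 4 pairs, adjusted p = 0.00145; adjusted p = 0.0845 with an estimated correlation). That call was lost without uninduced replicate 2, which left its partner unpaired (-0.10, adjusted p = 0.111), and on slides 1 and 2 alone (-0.12, adjusted p = 0.0766). Its members called over all genes numbered 0, 1 and 4 in the same order, and adjusted over the list alone 2, 4 and 6 were lower and 0, 0 and 1 higher. Ptgs2, the inducible cyclooxygenase, passed with the slide block (-0.78, adjusted p = 0.0146), and Tnfaip3, an NF-kB inhibitor (-0.52, adjusted p = 0.00759), Lif (-0.47, adjusted p = 0.0253) and Il11 (-0.38, adjusted p = 0.0206), both cytokines of the interleukin-6 family, with the replicate block, each lower in 4 of 4 pairs. Il11 was chosen after its values were seen. Irf1, an interferon pathway factor in the same list, was that higher member (0.32, adjusted p over the list alone = 0.00509 with the replicate block, higher in 4 of 4 pairs) and was not called over all genes.

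**Figure D2:**
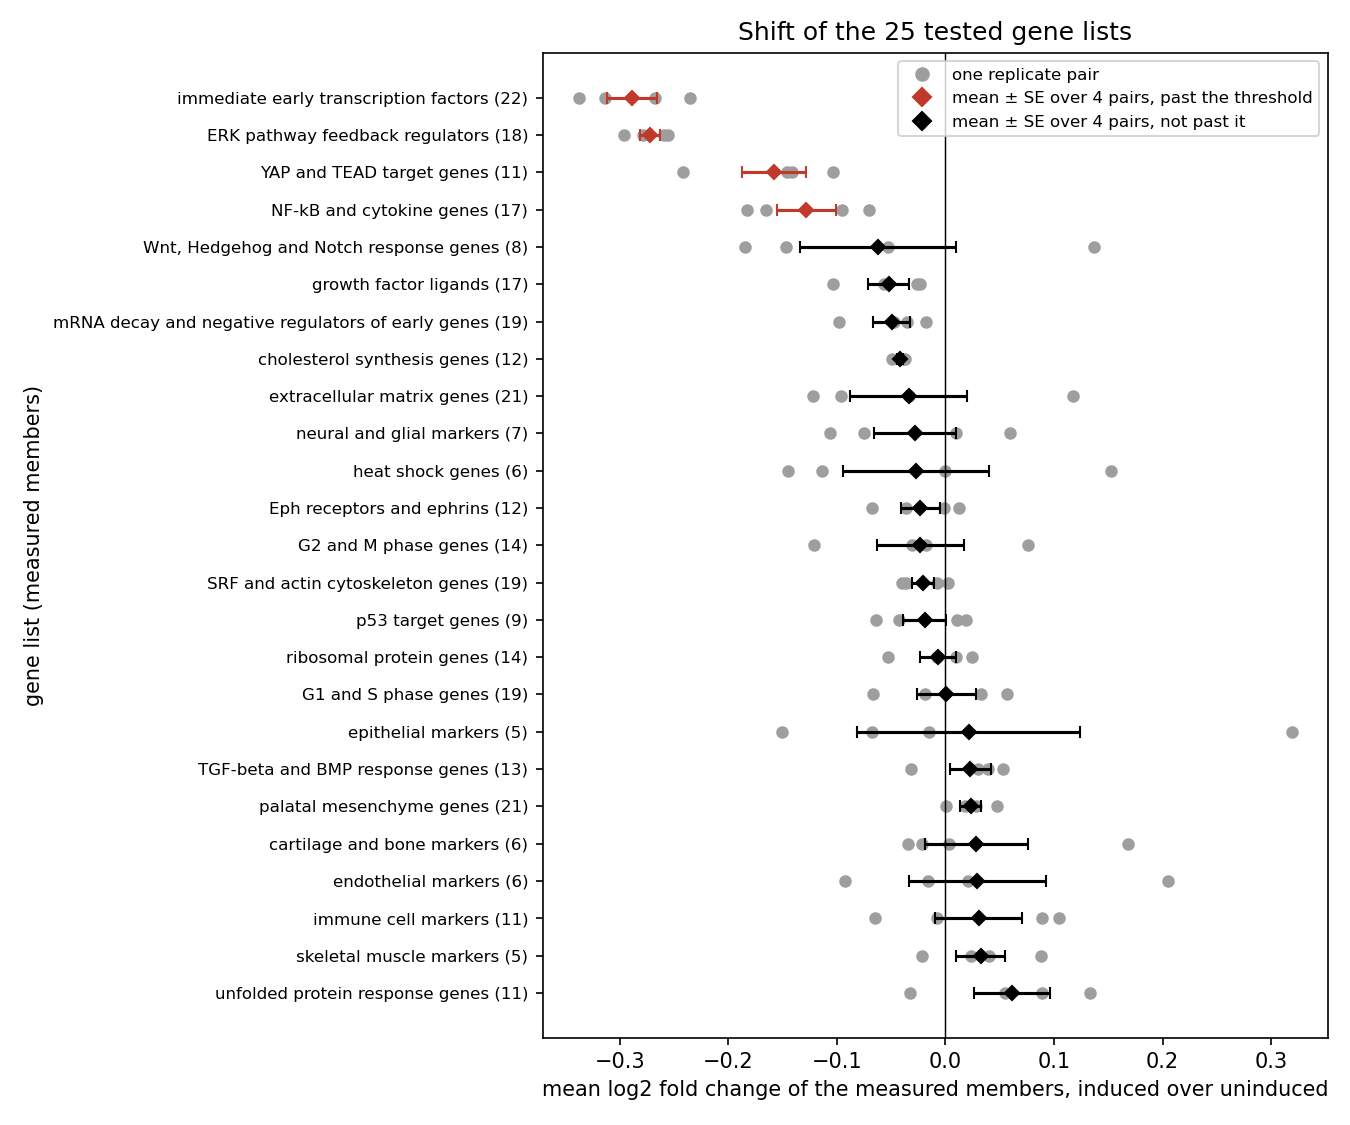
Mean log2 fold change of the measured members, induced over uninduced (horizontal axis), for the 25 tested gene lists (vertical axis, number of measured members in brackets), with grey dots for single replicate pairs and diamonds for the mean ± SE over 4 pairs, red where camera without a block passed. The 4 red lists have means from -0.29 to -0.13, and the other lists lie between -0.06 and 0.06.

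None of the other 21 tested lists passed without a block, with adjusted p from 0.416 to 0.885. Over all genes limma called 0 of their members without a block, 1 lower with the slide block and 5 lower with the replicate block, and 0 higher in each fit. Adjusted over the list alone, 0 were higher and 2 lower without a block, 4 higher and 8 lower with the slide block, and 7 higher and 12 lower with the replicate block. The unfolded protein response list had a mean of 0.06 and passed with the slide block (adjusted p = 0.0443) and the replicate block (adjusted p = 0.0425), higher in 3 of 4 pairs, though not with an estimated correlation (adjusted p = 0.301 and 0.679). Its member Chac1, which degrades glutathione, was higher with the replicate block when adjusted over the list alone (0.28, adjusted p = 0.00468, higher in 4 of 4 pairs). Mean log2 differences were -0.02 for the SRF and actin cytoskeleton list, -0.05 for growth factor ligands, -0.05 for mRNA decay and negative regulators of early genes, 0.02 for TGF-beta and BMP response genes and -0.06 for Wnt, Hedgehog and Notch response genes. Id2, a BMP target of the TGF-beta and BMP list, and Gadd45b, a stress-inducible member of the list of negative regulators, had differences of 0.35 and 0.33. Adjusted over the list alone both were higher with either block, as was Hey1, a Notch and BMP target of the first list (0.25), each in 4 of 4 pairs (slide block adjusted p = 0.0322, 0.0101 and 0.0322 for Id2, Gadd45b and Hey1). The G1 and S phase list had a mean of 0.00087 and the G2 and M phase list -0.02. The palatal mesenchyme list had a mean of 0.02. Its members Osr2 and Shox2, transcription factors of palate growth, had differences of 0.25 and 0.14, and Osr2 was higher with the replicate block when adjusted over the list alone (adjusted p = 0.0195, higher in 4 of 4 pairs). The means were -0.03 for extracellular matrix, -0.03 for heat shock, -0.02 for p53 target, -0.04 for cholesterol synthesis and -0.0067 for ribosomal protein genes. Has2, a hyaluronan synthase of the matrix list, was lower with the replicate block (-0.47, adjusted p = 0.00205, lower in 4 of 4 pairs). Leaving out 1 array brought cholesterol synthesis (-0.14, adjusted p = 0.0199, without induced replicate 3) and palatal mesenchyme (0.06, adjusted p = 0.045, without uninduced replicate 3) past the threshold. Both fits had no block and left the partner of that array unpaired. Per pair the cholesterol synthesis mean lay between -0.050 and -0.038, and the palatal mesenchyme mean between 0.0002 and 0.047. Slide 3 alone brought extracellular matrix past the threshold (-0.11, adjusted p = 0.0305). Mean, median and test differed in sign for 4 lists. The G1 and S phase list had a median of -0.02 and its test pointed down, and the G2 and M phase list had a median of 0.00013 with its test pointing down. The endothelial list had a median of -0.04 with its test pointing up, and the ribosomal list had its test pointing up.

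Transcripts of several Eph receptors and of ephrin-B1 itself were present in these cells. For Ephb4, Ephb1, Ephb6 and Efnb1 the groups differed after 60 min by less than the SD within either group, at the brightest probe. Ephb4, a receptor tyrosine kinase for B-class ephrins, had the brightest of the EphB probes, with 11.08 ± 0.10 in uninduced and 11.13 ± 0.11 in induced cells (SD, n = 4), a difference of 0.04 (SE 0.083), and its other probe gave -0.09 (SE 0.096, lower in 4 of 4 pairs). Ephb1 differed by -0.05 (SE 0.16), Ephb6, a kinase-inactive family member, by 0.01 (SE 0.21) and Efnb1, the gene of ephrin-B1, by -0.07 (SE 0.13). Each had an adjusted p of 0.9999 and these probes were above background on all 8 arrays. The Ephb3 probe was not above background on any of the 8 arrays, and no probe was named Ephb2. As a list, 12 measured Eph receptors and ephrins had a mean of -0.02 (adjusted p = 0.787, lower in 3 of 4 pairs). Epha2, an A-class receptor, had a difference of -0.38 (SD 0.24 and 0.13, lower in 4 of 4 pairs) and the A-class ephrin Efna1 one of 0.28 (SD 0.18 and 0.12, higher in 4 of 4 pairs). Both were larger than the SD within groups. Neither was called over all genes with or without a block (adjusted p = 0.0981 and 0.186 with the replicate block). Adjusted over the list alone, 0 members were called without a block, and with either block Epha2 was lower and Efna1 higher (adjusted p = 0.0212 and 0.0399 with the slide block).

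As lists, markers of other cell types did not pass the test on all 8 arrays. The immune cell list passed without uninduced replicate 3 (0.17, adjusted p = 0.00987) and without induced replicate 1 (0.20, adjusted p = 0.00156). The skeletal muscle list passed without uninduced replicate 3 (0.26, adjusted p = 0.0302). These fits had no block, so leaving out 1 array left its partner unpaired. Per pair the immune cell mean was -0.065, -0.0078, 0.105 and 0.089. The skeletal muscle mean was 0.088, 0.040, 0.023 and -0.022. The mean log2 difference was 0.02 for epithelial, 0.03 for endothelial, 0.03 for immune cell, -0.03 for neural and glial, 0.03 for skeletal muscle and 0.03 for cartilage and bone markers. Kdr, a VEGF receptor of the endothelial list, was higher with the replicate block when adjusted over the list alone (0.37, adjusted p = 0.0474, higher in 4 of 4 pairs). Of the immune cell list, Laptm5, Fcer1g, C1qb, C1qc and Cd14, all found in macrophages, were above background on all 8 arrays. Aif1, Adgre1, Lyz2, Tyrobp, C1qa and Cd52 were above it on some arrays, Mrc1 on 1, and the 4 probes of Ptprc, the common leukocyte antigen, on 0. The interferon-stimulated list had 3 measured members with a mean of 0.05 and was not tested as a list (Bst2, 0.15, was higher with the replicate block adjusted over the list alone, adjusted p = 0.0228, in 4 of 4 pairs), and of the red blood cell list 0 members were measured. Bst2 had an SD of 0.93 in uninduced and 0.94 in induced cells. Its SE over the 4 pairs was 0.019. Leaving out an array or a pair gave a difference from -0.235 to 0.54, and leaving out 1 array left its partner unpaired.

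Slide, not treatment, separated the arrays most. The first principal component held 50.3% of the variance, of which 99% lay between slides and 0.0835% between treatments. Treatment explained 68.5% of the fourth component, which held 7.9% of the variance. Correlations between arrays of the same group ranged from 0.982 to 0.993, and those between the uninduced and induced array of one replicate number from 0.994 to 0.996. Both groups were on every slide.

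**Figure D3:**
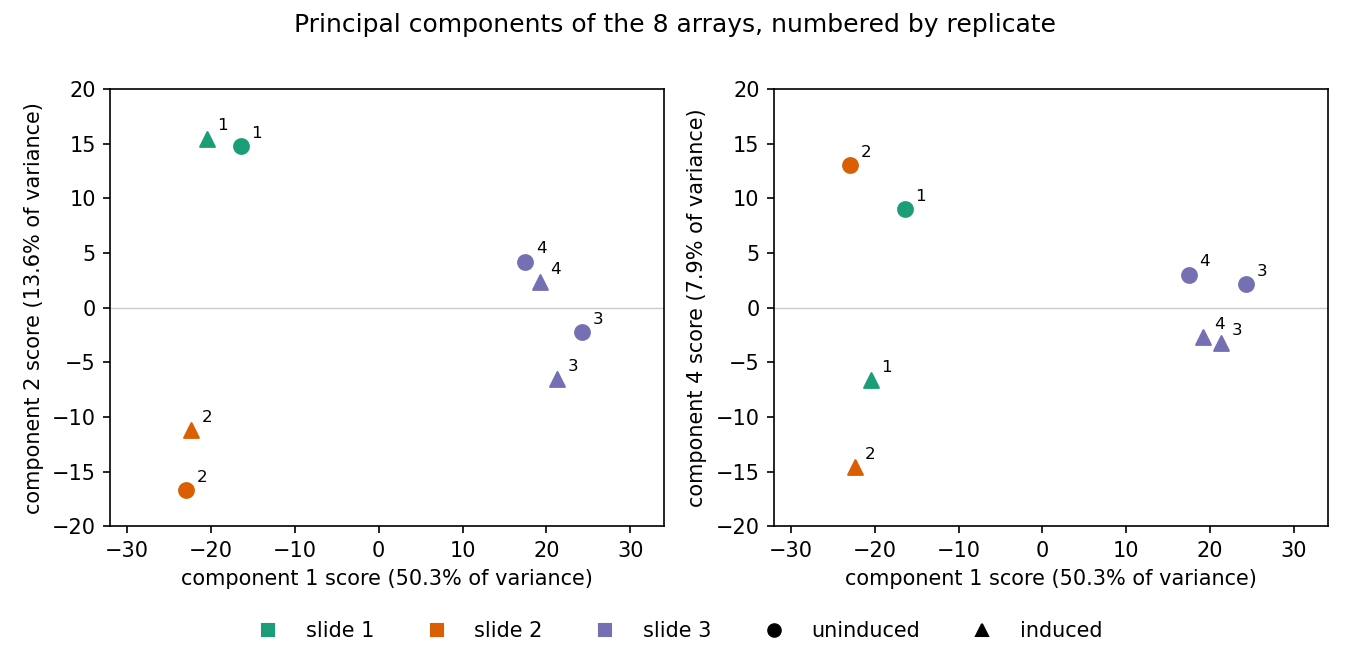
Scores of the 8 arrays on components 1 and 2 (left) and 1 and 4 (right), in log2 units, with colours for slides, circles for uninduced and triangles for induced arrays, and numbers for replicates. Slides 1 and 2 lie apart from slide 3 on component 1 (50.3% of the variance), and on component 4 (7.9%) all uninduced arrays lie above 0 and all induced arrays below it.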

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

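The comparison for a general loss of unstable transcripts, the 3 tests on Ccl4 and both tests on the slides were chosen only after the results were seen.

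Immediate early and ERK feedback genes lower in induced cells. In the raw signals the 40 measured members of both lists had a mean of -0.234 relative to the median of all genes (SE 0.0073 over 4 pairs), which argues against the normalization as the whole cause. A general loss of unstable transcripts was examined with 40 members of the TGF-beta and BMP, Wnt, Hedgehog and Notch, and mRNA decay lists. Their mean was -0.03 (SE 0.022), and the 2 early lists lay -0.253 (SE 0.026) from it. This cannot decide on such a loss, since no transcript half-life was used. The comparison also left out the YAP and TEAD (-0.16) and the NF-kB and cytokine (-0.13) lists, which were lower by camera with the preset correlation. Of the mRNA decay list itself 11 members were lower, among them Plk3 (-0.52) and Sgk1 (-0.27), and 8 were higher. Of all 35 splits of the arrays 1, the real one, reached its -log10 p for the immediate early list (16.97, highest other 7.9) and for the ERK list (12.5, highest other 5.13), but the numbers pair the arrays, and the 8 splits that part all 4 pairs are too few for a share under 0.05 (highest other 7.9 and 4.48; with the replicate block 18.2 against 6.78 and 14 against 3.58, each in 1 split). No biological source was tested, since no measure of ERK activity is given in the sources used here, and since the control's treatment is not described, an effect of the clustering reagent or of handling stays open too.

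Ccl4 higher in induced cells. A probe artefact is argued against by another Ccl4 probe, which differed by 1.61 against background (at least 1.92-fold). A larger share of immune cells is argued against by the mean of 11 immune cell markers, 0.03045 (SE 0.04). Per pair this mean lay between -0.065 and 0.105. The list passed without uninduced replicate 3 (0.17) and without induced replicate 1 (0.20), fits that left a partner array unpaired. Early activation of immune cells already present in both groups stays open: of 13 other genes of activated macrophages with a probe, 1 (Ccl3, at least 1.5-fold) was above background on at least 3 induced arrays with a lower bound over 0.5 on the log2 scale, and Il1b was at least 1.1-fold higher. Tnf, Il1a, Il10, Cxcl3, Ccrl2 and Clec4e stayed below background on all arrays, while Ptgs2 (-0.78, slide block adjusted p = 0.0146), Ccl2 (-0.21), both lower in 4 of 4 pairs, and Nfkbiz (-0.11, lower in 3 of 4 pairs), above background on all arrays, went the other way. Whether palate cells or immune cells made Ccl4, Ptgs2, Ccl2 or Nfkbiz was not tested, so the decreases do not decide on activation of immune cells. Bacterial products in a reagent stay open too.

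Arrays separate by slide. The gap between slides 1 and 2 and slide 3 on the first component was 40.55 among uninduced and 41.69 among induced arrays, a ratio of 0.973, which argues against a response to ephrin-B1 that differs between slides as the source. A hybridisation batch and separate cell preparations cannot be told apart as sources of the first component (50.3% of the variance), since no label gives a preparation.

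For the genes called without a block chance cannot be excluded: 3 of 35 splits gave at least the real 3 genes, and the highest other, 2531, parted slides 1 and 2 from slide 3 and so points to a structure of the samples. The other such split parted no pairs; among the 8 splits that part all 4 pairs, the real one gave 3 and the highest other 0. With the replicate block the 8 splits are too few for a share under 0.05, with 50 genes in the real split (1 split) and 0 in the highest other.

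Single arrays stood apart from the 3 others of their group in 7 of 232 groups of 4 values, where chance gives about 1 in 20, or 11.6. Egr2 was low in uninduced replicate 3, at 7.422 against 7.998 to 8.078. Ankrd1 was low in induced replicate 2, at 8.023 against 8.46 to 8.50. Pdgfa was high in induced replicate 4, at 11.89 against 11.80 to 11.82. Tnc, a matrix protein, was high in induced replicate 4, at 12.22 against 11.49 to 11.58. Cenpe, a mitotic motor, was low in uninduced replicate 2, at 10.15 against 10.34 to 10.37. Efnb2, the gene of ephrin-B2, was low in uninduced replicate 2, at 8.829 against 8.99 to 9.01. Irf7 was low in induced replicate 4, at 5.18 against 5.62 to 5.71.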

How the results depend on the processing

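The combinations of the replicate block with another choice were chosen after the data were seen. No result reversed. The immediate early list kept its direction and call in all 27 alternatives (-0.33 to -0.22). The ERK feedback list (-0.31 to -0.22) kept its direction in 27 and its call in 25, and lost it at -0.272 with an estimated correlation (adjusted p = 0.0845) and with fry (adjusted p = 0.196). Genes higher (1 as reported) were 2 with the slide block, 4 with the replicate block, 0 on slide 3 alone (65 with an unadjusted p under 0.05 in limma) and 0 with detection p under 0.01 on all 8 arrays (12), a filter that removes Ccl4, and 1 to 6 on leaving out an array or a pair (6 without replicate 3 and 3 without replicate 4, with the slide block). Genes lower (2 as reported) were 10 with the slide block, 46 with the replicate block, 1 with the mean of all probes, and 0 with median scaling (41 unadjusted), without a trend (90), at adjusted p under 0.01 (87), on slides 1 and 2 alone (143) and on slide 3 alone (139). On leaving out an array or a pair they were 0 to 30: 1 without induced replicate 4, 0 without any other single array (73 to 137 unadjusted), and with the slide block 3 without replicate 1, 0 without replicate 2 (261 unadjusted), 30 without replicate 3 and 21 without replicate 4. Fewer arrays give fewer degrees of freedom; otherwise the cause was not tested.

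With the replicate block, 4 higher and 46 lower became 1 and 10 without a trend, where 11 of the 50 genes remained; 34 to 49 remained in the 7 other settings. Without replicate 1, 2, 3 or 4 the block gave 5, 2, 6 and 3 higher (2 to 6) and 29, 21, 30 and 21 lower (21 to 30), with 32, 19, 33 and 23 of the 50 shared. Of the list calls by camera with the preset correlation, the block changed that of the unfolded protein response genes alone (adjusted p = 0.0425); with an estimated correlation it brought the ERK feedback list past the threshold (adjusted p = 0.0443), and with fry that list (adjusted p = 0.00266) and cholesterol synthesis (adjusted p = 0.0086). Of the 23 other lists, 2 passed as reported, 0 with an estimated correlation or with fry, 1 on slides 1 and 2 alone, and 1 to 5 on leaving out an array (1 without uninduced or induced replicate 2, 5 without uninduced replicate 3). The fits without 1 array had no block, so the partner of that array stayed unpaired. For the 116 named genes, 2781 of 2874 alternatives gave the same call, 27 lost it (13 each for Spry4 and Dusp6, 1 for Ccl4) and 66 gained it; 131 sign changes were in 42 genes not called. Signal over background limits Ccl4, whose fold is a lower bound.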

Other observations

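The macrophage list with its genes other than Ptgs2, and Nppb, Rgs16, Adm and Stc1, were chosen after their values were seen. Ccl3, a chemokine next to Ccl4 in function, was above background on 0 of 4 uninduced and 3 of 4 induced arrays and was at least 1.5-fold higher. Il1b, an inflammatory cytokine, was above background on the same numbers of arrays and at least 1.1-fold higher. Neither probe was kept for the test. Cxcl2, a chemokine for neutrophils, was above background on 1 induced array, and Ccl2, a chemokine for monocytes, had a difference of -0.21 and was lower in 4 of 4 pairs without being called over all genes. Ccl2, Nfkbiz and Ptgs2 of this list were above background on all 8 arrays and also belong to the NF-kB and cytokine list.

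Some of the 46 genes lower with the replicate block lie outside the early lists. They were not tested as a group, and each was lower in 4 of 4 pairs. Nppb, a natriuretic peptide, had a difference of -0.68 (adjusted p = 0.000108), Rgs16, a regulator of G protein signaling, -0.49 (adjusted p = 0.00229), Adm, the vasodilator adrenomedullin, -0.45 (adjusted p = 0.0144), and Stc1, a secreted glycoprotein, -0.37 (adjusted p = 0.0225). Plk3, a stress-responsive kinase, had -0.52 (adjusted p = 0.00292), Sgk1, a kinase induced by serum, -0.27 (adjusted p = 0.0346), and Mdm2, the p53 ubiquitin ligase, -0.23 (adjusted p = 0.0378). Probes without a single gene name were tested over all 16514 probes: 0 passed without a block, 1 was lower with the slide block and 3 with the replicate block. The one lower with both blocks had a difference of -0.84 (lower in 4 of 4 pairs, adjusted p = 0.0643 without a block).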
